A study of Homo sapiens with 6 samples.

How the data were processed

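RNA of TE-1 cells was measured on 6 1-colour Agilent arrays of design 026652, for 3 samples with 0 nM and 3 with 150 nM bortezomib for 24 h, per the labels. Per the labels' protocols, total RNA was amplified to Cy3-labelled cRNA. The deposited scanner files hold intensity values that Agilent Feature Extraction 11.0.1.1 made, per the file headers and the submitters' processing notes. Per the file headers, the processed signal is the spot intensity after background subtraction and spatial detrending, on a linear scale and not normalized between arrays. The value table deposited with the series holds log2 values of 28574 probes (83.7% of the probes). How it was made is not given in the sources used here. Its columns have nearly identical quantiles with medians of 7.94, and each matched its own array best, with r from 0.9997 to 0.9998 across probes, which is how scale and direction were found. Group differences from the table and from the scanner files correlated at 0.983 across probes. The table was used as an alternative only.

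On each array 43118 non-control spots were read and 1377 control spots left out. Spots that the software marked as non-uniform or as population outliers (279 to 352 per array) were left out. The main values were log2 of the processed signal minus each array's 75th percentile of it, with spots of a probe averaged. A probe entered where over a share of 0.5 of its spots were well above background on all 3 arrays of at least 1 group. A gene was represented by its entering probe with the highest mean over all arrays. Probes were named by unversioned accession through the NCBI RefSeq gene table of assembly GRCh38.p14, used for names only because the array design names hg19. Of 26599 probes with a RefSeq accession 25769 matched. In all 25771 of 34127 probes (75.5%) received a symbol, and 8356 kept the identifier of the file. Of the 22696 genes tested, 16928 have a symbol. The rest were tested as single features and are counted but not named.

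Signal over background set what could be measured. Probes well above background numbered 28374, 28869 and 27833 on vehicle arrays 1 to 3, and 28802, 28059 and 27534 on bortezomib arrays 1 to 3. The 75th percentile of the processed signal was 1872, 2254 and 1897 on the vehicle arrays and 1761, 1986 and 1815 on the bortezomib arrays. No probe was saturated. Genes not well above background on any array of 1 group (41 called genes for vehicle and 100 for bortezomib) have a bound in place of a fold.

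Before the data were examined, the comparison, tests, gene lists, rule for named genes and most alternatives were fixed, with 3 samples against 3. Replicate 3 of each group then proved to be a second scan of the array of replicate 1. Beside the correlation of spot deviations, non-uniform spots coincided (16 shared by vehicle 1 and 3, which had 21 and 19, and 29 shared by bortezomib 1 and 3, which had 40 and 41, against at most 10 in other pairs). Differences of 13676 single-spot probes had an SD of 0.0426 and 0.0356, under the noise of 0.0754 and 0.0893 expected from replicated spots, while other pairs within a group had 0.228 to 0.272. Both scans were therefore averaged, which leaves 2 samples per group and 2 residual degrees of freedom. This change was made after seeing the data, from spot noise and not from the calls, and the fit of all 6 arrays as separate replicates is given as an alternative. The file headers place both arrays numbered 3 in a second scan on another day, taken as the slide block. It holds 1 array of each group, so within it there is no test.

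Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested, an adjusted p under 0.05 and, for size, an absolute log2 difference of at least 1. The 36 gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and adjusted over the lists, and again with an estimated correlation and with fry. With an estimated correlation none of the 20 list calls held: 2 of 36 lists had an unadjusted p under 0.05, and the smallest adjusted p was 0.294. That setting takes p-values on the 2 residual degrees of freedom, where the preset one uses nearly as many as there are genes. Named genes were chosen by rule. They are the 12 highest and 12 lowest called genes with a symbol and above background on all arrays, up to 4 called members per list with the largest absolute difference plus members needed to say what did not pass, 18 genes fixed in advance (such as PSMB5, DDIT3 and MYC), up to 5 genes per direction with the largest bounds, and 5 reference genes. Some genes that the rule takes are not reported here. DERL3, UBQLN2, JUND, SPRY1, TRAF1, SLC30A1, HSP90AA1, HSP90AB1 and RPS20 stand in the text as list members, some of them singled out after their values were seen. So do the fibroblast markers COL1A1, COL1A2, COL6A3, PDGFRA, POSTN and THY1.

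Alternatives fixed in advance were normexp background correction, quantile, median and detected-probe scaling, the value table, other filters, other rules for spots and probes, a variance trend with robust fitting, the replicate number as a block, the slide as a block and leaving out each sample. The files hold median signals but no mean signals, so normexp ran on the median signal with the median local background. Added after seeing the data were the fit of all 6 arrays as separate replicates, the first scan alone, normexp with the background taken from 153 negative control spots, and crossed replicate numbers as a block. Leaving out a sample leaves out both scans of its array. The pairing of replicate numbers was checked by the correlation of deviations from group means.

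The test was checked on simulated data with the spread of these samples, in which 50 genes of each of 4 sizes among 22696 were changed. None of the genes changed by 0.5 or by 1 on the log2 scale was called, 36% of those changed by 2 and 74% of those changed by 4 were, and 1 of 56 calls was false. Of the simulated lists, 2 of 2 shifted by 0.5 and 1 of 34 others were called. Genes were simulated independently of each other, so the check says nothing of list calls where members are correlated. Far fewer genes were changed than the 6643 called in the real data. The adjustment was therefore stricter, and the percentages do not carry over.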

Results

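Gene expression was measured in TE-1, an established human cell line of esophageal carcinoma with epithelial character, after 24 h with 150 nM bortezomib or with an equal volume of vehicle (phosphate-buffered saline). Bortezomib is a boronic acid drug that blocks the proteasome, the complex that degrades ubiquitin-tagged proteins, by binding its PSMB5 subunit. The series title states that the drug's toxic effect on these cells was the question. The labels give 3 samples per group, each on a 1-colour array hybridised with Cy3-labelled cRNA. Replicates 1 and 3 of each group differed by less than the sampling noise and were counted as 1 sample, so that n = 2 per group. The evidence came from the spots themselves. Across 645 probes printed more than once, deviations of single spots from their probe's mean correlated at 0.857 between vehicle 1 and vehicle 3 and at 0.922 between bortezomib 1 and bortezomib 3, against at most 0.605 in any other pair of arrays. Nothing in the labels says that the samples of a group were independent cultures beyond treatment in triplicate. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Those of gene lists in camera set the members against the other genes, under a preset correlation of 0.01, and do not measure replication between samples. Of 34127 probes, 80.7% to 84.6% were well above background on each array, none was saturated, and the small number of arrays limits the precision.

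**Figure D1:**
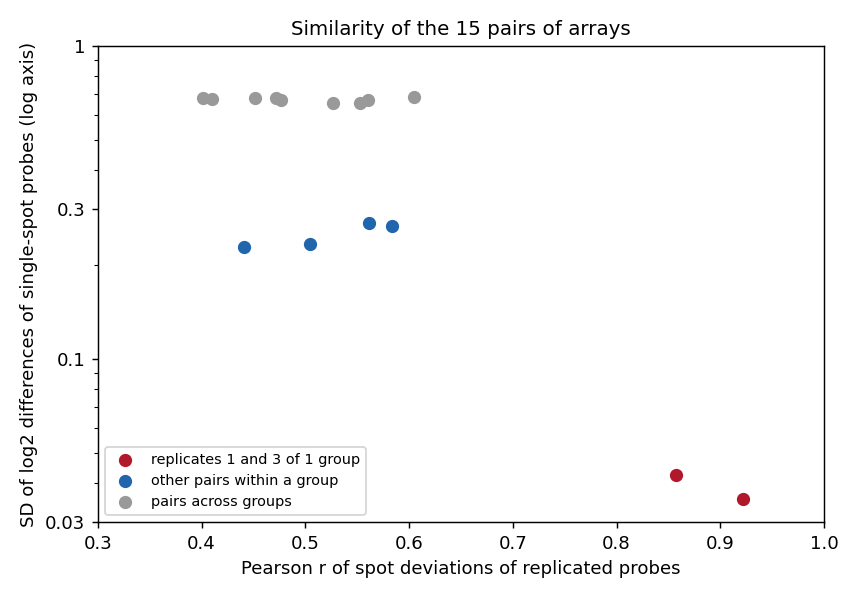
Each point is 1 of the 15 pairs of arrays, with Pearson's r of spot deviations of replicated probes (across 645 probes) on the horizontal axis and the SD of log2 differences of single-spot probes on a log vertical axis. The pairs of replicates 1 and 3 (red) stand apart at r of 0.857 and 0.922 and an SD of 0.0426 and 0.0356, against an SD of 0.228 to 0.272 in the other pairs within a group (blue).

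With bortezomib, all 14 genes of the proteasome's core, all 19 of its regulatory particle, 20 of 26 heat shock genes and 18 of 29 genes of the ATF4 stress response rose, and 19 of 30 replication-dependent histone genes, 8 of 11 genes of the metallothionein list and 7 of 8 measured fibroblast markers fell. As groups these lists passed in camera with its preset correlation but not with one estimated from the data (adjusted p from 0.294 to 0.353). The estimates ranged from -0.13 for the fibroblast markers to 0.24 for the ATF4 response, against the preset 0.01. That of the histones was 0.015. A higher correlation is therefore not the whole reason why the histone and fibroblast calls were lost. Camera with an estimated correlation also uses only the 2 residual degrees of freedom, which leaves it little power over 36 lists. The gene with the largest rise among those measurable on all arrays was IL1A, which encodes the inflammatory cytokine interleukin 1 alpha. Its log2 level went from -7.75 ± 0.29 (SD, n = 2) with vehicle to -3.29 ± 0.18 with bortezomib, a 22.1-fold difference. On vehicle arrays 1 to 3 IL1A was at -7.52, -7.96 and -7.59. The lowest levels well above background there were -7.91, -8.28 and -7.77, so the size of this fold is uncertain. The largest fall was in RAB26, a small GTPase of secretory vesicles, from 1.83 ± 0.11 to -2.26 ± 0.10, which is 17.1-fold lower. In limma's moderated test 3086 of 22696 genes rose and 3557 fell at an adjusted p under 0.05. Of these, 855 rose and 1575 fell at least 2-fold.

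Among the 12 genes with the largest rises, all past the threshold in limma (adjusted p from 0.00453 to 0.00547), were further secreted and stress-associated products. Differences in log2, bortezomib minus vehicle, are given with the standard error of the fit. IL11, a cytokine of the interleukin 6 family, rose by 3.99 ± 0.15 (15.9-fold), and GDF15, a cytokine released by stressed cells, by 3.77 ± 0.13 (13.7-fold). HSPA1B, an inducible cytosolic HSP70 chaperone, rose 15.9-fold (3.99 ± 0.15), although its probe and that of its near-identical copy HSPA1A may read both. DDIT3, the stress transcription factor CHOP, rose 11.8-fold (3.56 ± 0.15), and CHAC1, which breaks down glutathione, 7.41-fold (2.89 ± 0.13). CYP4F3, which inactivates leukotrienes, rose 16.9-fold (4.08 ± 0.20), and the calcium-binding protein gene CALB1 15.5-fold (3.95 ± 0.13). The vehicle values of CYP4F3 (-7.28, -7.93 and -7.57) also lay near the lowest levels well above background, so its fold is uncertain. FAM241B, TRIM54 and the microtubule-binding protein gene MAP1B rose 10.8-fold, 8.84-fold and 7.80-fold.

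The 12 genes with the largest falls all had a limma adjusted p of 0.00453. After RAB26 came the methyltransferase gene TMT1A, 16.5-fold lower (-4.04 ± 0.10), FNDC10, 15.8-fold lower (-3.98 ± 0.11), and NREP, 14.6-fold lower (-3.87 ± 0.12). The transcription factor gene FOXN4 was 13.6-fold lower and the ephrin receptor gene EPHA7 11.8-fold lower. UBD, which encodes a ubiquitin-like modifier that targets proteins to the proteasome, was 10.7-fold lower (-3.43 ± 0.13), as was ASB9. HPGD, the enzyme that inactivates prostaglandins, was 10.5-fold lower (-3.39 ± 0.15). VIT, H6PD and the potassium channel gene KCNJ16 were 9.56-fold, 9.45-fold and 9.35-fold lower. In each of the 24 genes of both groups every bortezomib array lay on the same side of every vehicle array. Their choice by size all but ensured this, and the arrays include repeat scans. Some called genes were not well above background on any array of 1 group and have only a bound, taken as the bright group's mean against, on each array of the other group, the lowest signal well above background or the probe's own signal, whichever was higher. BEST1 was at least 11.8-fold higher with bortezomib, LINC00520 at least 10.1-fold, SPX at least 6.49-fold, SPP1 (osteopontin) at least 5.90-fold and LAYN at least 5.10-fold. PSAPL1 was at least 10.7-fold lower, PTH2R at least 8.18-fold and TMEM129 at least 6.96-fold.

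The 20S core of the proteasome, which holds its proteolytic sites, rose as a group. All 14 measured genes passed (14 adjusted over the list alone), the median log2 difference was 1.01, and camera gave an adjusted p of 1.74e-08 with its preset correlation (adjusted p = 0.294 with an estimated correlation). PSMB7 rose 3.14-fold (1.65 ± 0.09), PSMB6 2.33-fold (1.22 ± 0.11) and PSMB5, the drug's binding site, 2.07-fold (1.05 ± 0.12). The 19S regulatory particle, which receives and unfolds ubiquitin-tagged proteins, rose in all 19 genes (19 adjusted over the list alone), with a median of 1.30 and a camera adjusted p of 7.78e-11 (adjusted p = 0.294 with an estimated correlation). The ATPase gene PSMC4 rose 4.31-fold (2.11 ± 0.11), PSMD12 by a log2 difference of 2.00 ± 0.09 and the deubiquitinase gene PSMD14 3.64-fold (1.86 ± 0.11). Genes for ubiquitin and for the VCP segregase with its partners rose in 12 and fell in 1 of 25 (15 and 1 adjusted over the list alone), with a median of 0.55 and a camera adjusted p of 3.43e-05 (adjusted p = 0.294 with an estimated correlation). ZFAND2A, an arsenite-inducible proteasome-associated protein gene, rose 6.03-fold (2.59 ± 0.12), the VCP cofactor genes NSFL1C and UFD1 rose 3.18-fold and 2.96-fold, and UBQLN2 fell. The polyubiquitin gene UBB rose 1.59-fold (0.67 ± 0.10), and its probe may also read ubiquitin repeats of other genes.

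Neither of the other proteasome lists passed in camera. Among proteasome assembly factors and activators 4 of 12 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of 0.11 and a camera adjusted p of 0.586, although fry called the list higher (adjusted p = 0.0213). The maturation factor gene POMP rose 2.90-fold (1.54 ± 0.10), and the assembly chaperone gene PSMG4 was 2.04-fold lower (-1.03 ± 0.11). Of the 5 immunoproteasome genes none rose and 2 fell (2 adjusted over the list alone), with a median of -0.22 and a camera adjusted p of 0.269. The catalytic subunit genes PSMB9 and PSMB8 were 1.77-fold and 1.48-fold lower.

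Cytosolic heat shock genes rose in 20 of 26 and fell in none (24 and 0 adjusted over the list alone). Their median was 1.11 and the camera adjusted p 2.22e-11 (adjusted p = 0.294 with an estimated correlation). HSPA1A rose 4.95-fold (2.31 ± 0.12), the small heat shock protein gene HSPB8 4.56-fold (2.19 ± 0.18), CHORDC1 3.54-fold and the HSP40 gene DNAJB1 3.37-fold (1.75 ± 0.12). The co-chaperone gene BAG3 rose 2.46-fold (1.30 ± 0.25), and HSPA6 rose 1.49-fold (0.57 ± 0.10). The HSP90 genes HSP90AB1 and HSP90AA1 did not pass over all genes, at 0.62 ± 0.16 and 0.43 ± 0.12. Chaperones of the endoplasmic reticulum and genes of its degradation pathway rose in 15 and fell in 1 of 25 (18 and 1 adjusted over the list alone), with a median of 0.55 and a camera adjusted p of 1.47e-06 (adjusted p = 0.294 with an estimated correlation). DNAJC3 rose 3.17-fold (1.66 ± 0.10), HSPA5, which encodes BiP, 2.55-fold (1.35 ± 0.13), HERPUD1 2.31-fold and DNAJB9 2.03-fold, while DERL3 fell.

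Genes of the integrated stress response controlled by ATF4 rose in 18 of 29 and fell in none (19 and 0 adjusted over the list alone), with a median of 1.00 and a camera adjusted p of 1.93e-09 (adjusted p = 0.311 with an estimated correlation). Besides GDF15, DDIT3 and CHAC1, the asparagine synthetase gene ASNS rose 6.22-fold (2.64 ± 0.12) and ATF3 4.61-fold (2.21 ± 0.14). ATF4 itself rose 2.10-fold (1.07 ± 0.13). Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose in 12 of 20 and fell in none (12 and 1 adjusted over the list alone), with a median of 0.60 and a camera adjusted p of 0.000532 (adjusted p = 0.294 with an estimated correlation). WARS1 rose 3.26-fold (1.71 ± 0.14), CARS1 2.68-fold (1.42 ± 0.30), SARS1 2.36-fold and GARS1 2.19-fold. Autophagy and lysosome genes rose in 11 of 23 and fell in none (11 and 1 adjusted over the list alone), with a median of 0.45 and a camera adjusted p of 0.000508 (adjusted p = 0.294 with an estimated correlation). GABARAPL1 and MAP1LC3B, which coat autophagosomes, rose 3.08-fold (1.62 ± 0.10) and 2.39-fold (1.26 ± 0.10), the protease gene ATG4A 2.47-fold, and SQSTM1, the ubiquitin-binding receptor p62, 2.08-fold (1.06 ± 0.22).

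Immediate early genes, among them AP-1 transcription factors, rose in 15 and fell in 1 of 21 (17 and 1 adjusted over the list alone). Their median was 0.89 and the camera adjusted p 1.63e-07 (adjusted p = 0.294 with an estimated correlation). JUN rose 6.59-fold (2.72 ± 0.14), KLF2 4.57-fold (2.19 ± 0.14) and MAFF 4.50-fold (2.17 ± 0.14), JUND fell, and MYC was at -0.06 ± 0.10 and did not pass. Target genes of MAP kinase signalling, most of them negative feedback regulators, rose in 7 and fell in 2 of 16 (7 and 3 adjusted over the list alone). Their median was 0.30 and the camera adjusted p 0.0217 (adjusted p = 0.311 with an estimated correlation). The phosphatase genes DUSP1 and DUSP5 rose 4.32-fold (2.11 ± 0.10) and 3.90-fold (1.96 ± 0.10), SPRY4 rose 4.10-fold and ETV5 5.49-fold (2.46 ± 0.46), whereas SPRY1 was 3.64-fold lower. NF-kB target genes rose in 9 and fell in 2 of 20 (10 and 2 adjusted over the list alone), with a median of 0.32 and a camera adjusted p of 0.0415 (adjusted p = 0.387 with an estimated correlation). Besides IL1A, RELB rose 3.54-fold (1.82 ± 0.16), the chemokine gene CXCL2 3.08-fold (1.62 ± 0.12) and TRAF1 at least 2.06-fold, while the chemokine gene CCL20 was at least 4.04-fold lower, a call that ended in 2 of the 4 fits without 1 sample (vehicle SD 1.02, and a smaller log2 difference of -1.47 without vehicle replicate 2). The list's call ended in 12 of 23 other settings (camera or fry adjusted p from 0.0116 to 0.131), and that of the feedback genes in 2 of 23 (0.00893 to 0.110).

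**Figure D2:**
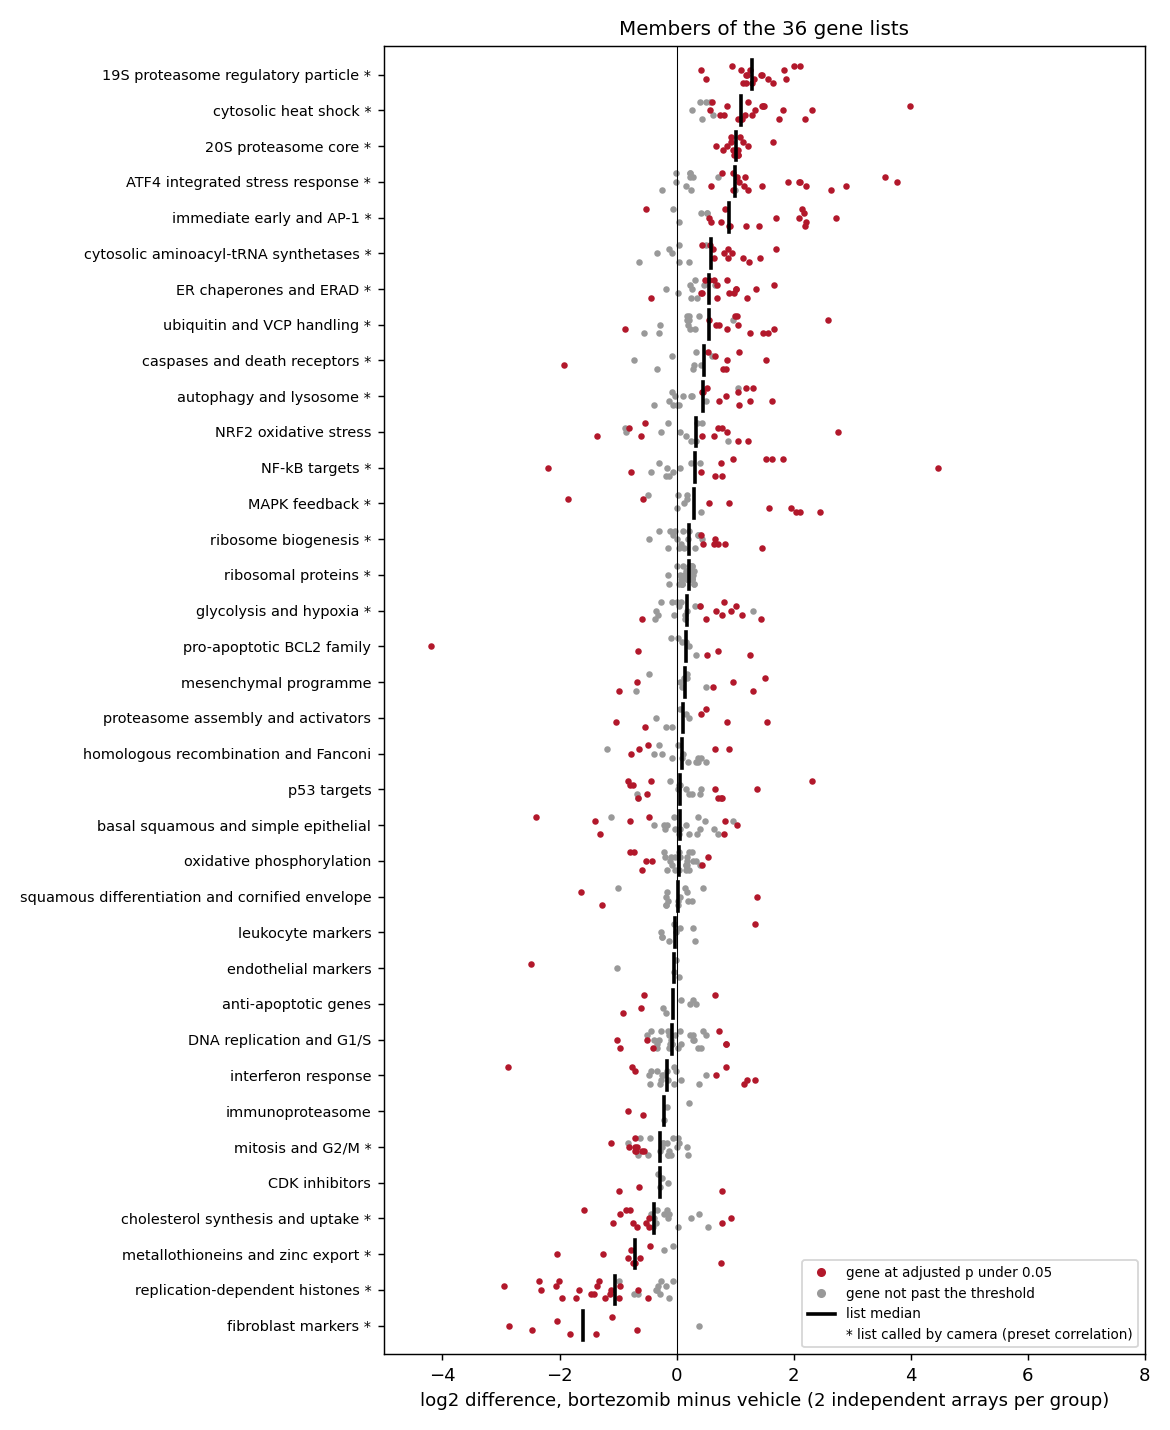
Log2 difference, bortezomib minus vehicle, of each measured member (points) of the 36 gene lists, with the list's median (bar). Red points passed limma's adjusted p threshold, and an asterisk marks lists called by camera with its preset correlation. The 19S list has a median of 1.30 and the fibroblast marker list one of -1.60.

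Replication-dependent histone genes, which supply the nucleosomes of newly made DNA, fell in 19 of 30 and rose in none (23 and 0 adjusted over the list alone), with a median of -1.06 and a camera adjusted p of 4.47e-10 (adjusted p = 0.294 with an estimated correlation). H2BC21 was 7.76-fold lower (-2.96 ± 0.18), H2AC8 5.10-fold (-2.35 ± 0.10), H2AC6 4.98-fold (-2.32 ± 0.13) and H2AC7 4.19-fold (-2.07 ± 0.11). Histone genes are so alike that a probe may read several. Genes of mitosis fell in 9 of 29 and rose in none (9 and 0 adjusted over the list alone). Their median was -0.29 and the camera adjusted p 0.000651 (adjusted p = 0.294 with an estimated correlation). The median ranged from -0.46 to -0.11 under 5 other scalings. The kinesin genes KIF20A and KIF11 were 2.17-fold (-1.12 ± 0.11) and 1.64-fold lower, the kinase gene AURKB 1.75-fold and the topoisomerase gene TOP2A 1.64-fold. DNA replication genes did not pass as a list: 3 rose and 4 fell of 33 (3 and 2 adjusted over the list alone), with a median of -0.07 and a camera adjusted p of 0.801. E2F2 was 2.03-fold lower, and GINS3 and ORC6 rose 1.81-fold and 1.80-fold.

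Metallothioneins, small proteins that bind zinc and copper, fell in 8 of 11 genes of their list (8 adjusted over the list alone), with a median of -0.72 and a camera adjusted p of 0.00300 (adjusted p = 0.353 with an estimated correlation). MT1M was 4.10-fold lower (-2.04 ± 0.13) and MT1E 2.40-fold (-1.26 ± 0.10), and their close similarity leaves the assignment to single genes uncertain. The 1 member that rose was the zinc exporter gene SLC30A1, at 1.69-fold (0.75 ± 0.10). Genes of cholesterol synthesis and uptake fell in 10 and rose in 2 of 25 (13 and 3 adjusted over the list alone), with a median of -0.38 and a camera adjusted p of 0.0141 (adjusted p = 0.580 with an estimated correlation). The sterol reductase gene TM7SF2 was 2.98-fold lower (-1.57 ± 0.10), INSIG1 2.12-fold and LSS 1.95-fold. That call ended in 1 of 23 other settings, without bortezomib replicate 1 (camera or fry adjusted p from 0.000546 to 0.0765 over those 23 settings).

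Of 12 fibroblast markers, included as a check on other cell types in the cultures, 8 were measured, 7 fell and none rose (7 and 1 adjusted over the list alone). Their median was -1.60 and the camera adjusted p 0.000508 (adjusted p = 0.294 with an estimated correlation). The collagen gene COL3A1 was 7.29-fold lower (-2.87 ± 0.38), the receptor gene PDGFRB 5.55-fold (-2.47 ± 0.10), and the proteoglycan genes DCN and LUM 4.13-fold (-2.05 ± 0.13) and 3.52-fold (-1.81 ± 0.10). A wider list of mesenchymal genes did not pass in camera: 4 rose and 2 fell of 14 (4 and 3 adjusted over the list alone), with a median of 0.15 and a camera adjusted p of 0.269, although fry called the list higher (adjusted p = 0.00690). ZEB2 rose 2.86-fold (1.51 ± 0.16), CCN1 2.46-fold and ZEB1 1.94-fold, and TWIST1 was 1.97-fold lower. Of 10 measured leukocyte markers CD68, which is also a lysosomal protein of other cells, rose 2.54-fold and none fell (1 and 0 adjusted over the list alone). The leukocyte list had a median of -0.03, a mean of 0.10 and a camera adjusted p of 0.812, in the direction of the mean. Of 5 measured endothelial markers the angiopoietin receptor gene TEK was 5.60-fold lower (-2.49 ± 0.13) and none rose (2 fell adjusted over the list alone), with a median of -0.05 and a camera adjusted p of 0.269.

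Genes of the cells' own epithelial type did not pass as lists. Of 26 basal and simple epithelial genes 3 rose and 5 fell (3 and 5 adjusted over the list alone), with a median of 0.05, a mean of -0.06 and a camera adjusted p of 0.858. The transcription factor gene SOX2 was 5.27-fold lower (-2.40 ± 0.11), the integrin gene ITGB4 2.61-fold, and CDH1, which encodes E-cadherin, 2.46-fold (-1.30 ± 0.10), and the keratin gene KRT16 rose 2.05-fold. Of 17 squamous differentiation genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), with a median of 0.02, a mean of -0.12 and a camera adjusted p of 0.801. EMP1 rose 2.60-fold, and MAL and the cornified envelope gene CNFN were 3.09-fold and 2.41-fold lower.

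Among genes of cell death, caspases and death receptors rose in 7 and fell in 1 of 16 (9 and 3 adjusted over the list alone), with a median of 0.47 and a camera adjusted p of 0.0159 (adjusted p = 0.309 with an estimated correlation). TNFRSF10A, a receptor of the death ligand TRAIL, rose 2.89-fold (1.53 ± 0.16) and CASP9 2.09-fold, and the inflammatory caspase gene CASP1 was 3.79-fold lower (-1.92 ± 0.11). This call ended in 4 of 23 other settings (camera or fry adjusted p from 0.00430 to 0.0714). Pro-apoptotic members of the BCL2 family rose in 3 and fell in 2 of 11 (3 and 2 adjusted over the list alone), with a median of 0.15, a mean of -0.15 and a camera adjusted p of 0.512. PMAIP1, which encodes NOXA, rose 2.39-fold (1.26 ± 0.11), and BMF was at least 16.9-fold lower by the probe that represents it, although another BMF probe stayed above background. Anti-apoptotic genes rose in 1 and fell in 3 of 10 (1 and 3 adjusted over the list alone), with a median of -0.05 and a camera adjusted p of 0.801. BCL2 was 1.88-fold lower, BIRC2 rose 1.59-fold, and MCL1 was at 0.07 ± 0.12 and did not pass. Target genes of p53 rose in 6 and fell in 6 of 23 (7 and 7 adjusted over the list alone), with a median of 0.07 and a camera adjusted p of 0.635. GADD45A rose 4.96-fold (2.31 ± 0.16) and PLK3 2.59-fold, and BTG2 was 1.73-fold lower. CDK inhibitors rose in 1 and fell in 2 of 7 (1 and 2 adjusted over the list alone), with a median of -0.29 and a camera adjusted p of 0.203. CDKN1A, which encodes p21, rose 1.71-fold (0.78 ± 0.15) and CDKN2C was 1.98-fold lower.

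Oxidative stress genes controlled by NRF2 rose in 8 and fell in 4 of 23 (9 and 4 adjusted over the list alone), with a median of 0.33 and a camera adjusted p of 0.105, although fry called the list higher (adjusted p = 0.00423). The aldo-keto reductase gene AKR1B10 rose 6.73-fold (2.75 ± 0.15), the glutathione reductase gene GSR 2.32-fold and the heme oxygenase gene HMOX1 1.56-fold (0.65 ± 0.15), and the transporter gene ABCC3 was 2.55-fold lower. Genes of glycolysis and the hypoxia response rose in 9 and fell in 1 of 25 (9 and 1 adjusted over the list alone), with a median of 0.17 and a camera adjusted p of 0.0203 (adjusted p = 0.643 with an estimated correlation). The peptide hormone gene ADM rose 2.73-fold (1.45 ± 0.12) and ANKRD37 2.18-fold. Ribosome biogenesis genes rose in 7 of 25 and fell in none (7 and 0 adjusted over the list alone), with a median of 0.22 and a camera adjusted p of 0.0133 (adjusted p = 0.671 with an estimated correlation). RRP12 rose 2.74-fold (1.45 ± 0.30) and BYSL 1.77-fold. None of 35 ribosomal protein genes passed (0 adjusted over the list alone), although the list did, with a median of 0.20 and a camera adjusted p of 0.00275 (adjusted p = 0.560 with an estimated correlation). RPS20 was at 0.30 ± 0.11, and camera's direction turned downward with quantile normalization (median -0.004) and with the authors' value table (median 0.01). The glycolysis call ended in 7 of 23 other settings (camera or fry adjusted p from 0.00311 to 0.446), the biogenesis call in 4 (0.000848 to 0.301) and the ribosomal protein call in 4 (0.000119 to 0.755).

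Interferon response genes rose in 5 and fell in 3 of 24 (5 and 3 adjusted over the list alone), with a median of -0.16 and a camera adjusted p of 0.832. IFIT2 rose 2.54-fold (1.34 ± 0.13), and IFITM1 was 7.33-fold lower (-2.87 ± 0.17). Oxidative phosphorylation genes rose in 2 and fell in 5 of 30 (1 and 4 adjusted over the list alone), with a median of 0.05, a mean of -0.005 and a camera adjusted p of 0.785. NDUFB3, of respiratory complex I, was 1.74-fold lower and UQCRC2 rose 1.45-fold. Genes of homologous recombination and the Fanconi pathway rose in 2 and fell in 3 of 19 (2 and 3 adjusted over the list alone), with a median of 0.09, a mean of -0.009 and a camera adjusted p of 0.801. BRCA1 was 1.72-fold lower.

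**Figure D3:**
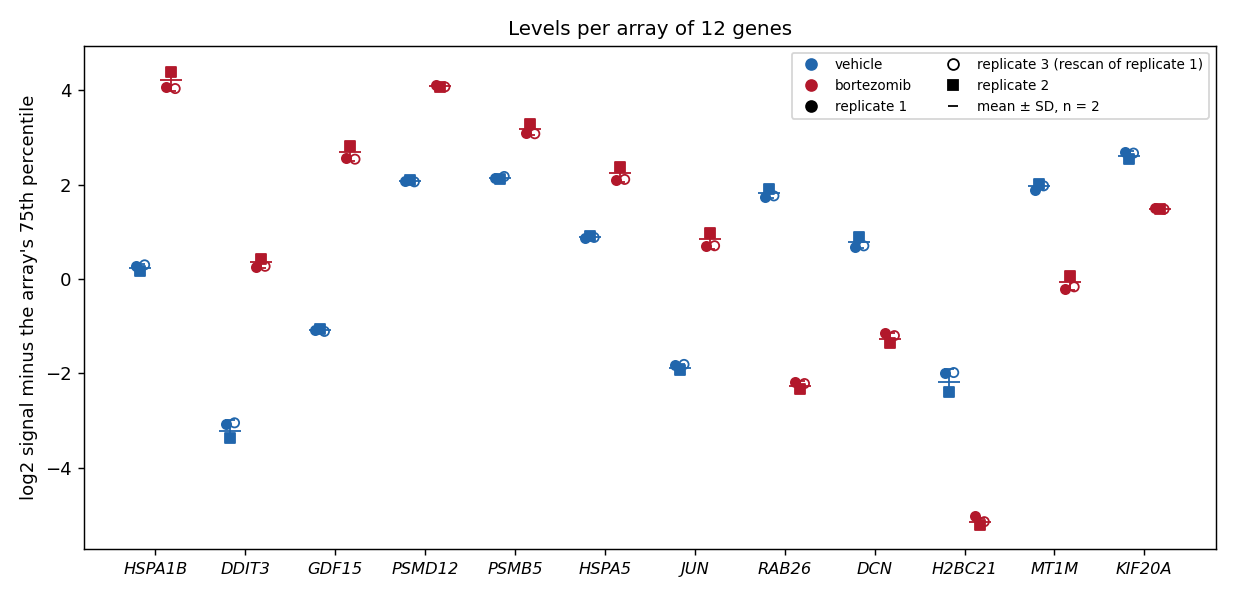
Log2 signal minus the array's 75th percentile of 12 genes on each array of the vehicle (blue) and bortezomib (red) groups, with the mean and SD of n = 2 samples (lines) and replicate 3 as an open circle. HSPA1B went from 0.23 ± 0.08 with vehicle to 4.22 ± 0.24 with bortezomib, and H2BC21 from -2.19 ± 0.29 to -5.15 ± 0.09.

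Of the reference genes, ACTB (0.18 ± 0.12), GAPDH (0.17 ± 0.11) and PPIA (0.01 ± 0.11) did not pass, while TBP rose 1.98-fold (0.99 ± 0.10) and HPRT1 1.33-fold (0.41 ± 0.09). The 3 that did not pass take the opposite sign under other scalings (the authors' value table for ACTB, that table and quantile normalization for GAPDH, and both and others for PPIA).

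The counts of genes fell when any 1 sample was left out. Such fits have 1 residual degree of freedom in place of 2. Lost power and the influence of a single sample can therefore not be told apart. Without vehicle replicate 1, a sample that includes its repeat scan, limma called 682 genes higher and 1241 lower, and without vehicle replicate 2 it called 739 and 1356. Without bortezomib replicate 1 and its repeat scan the counts were 1413 and 2092, and without bortezomib replicate 2 they were 1217 and 1916. In each of these fits the lone sample is assumed to vary like the other group. Of the 169 called genes named by rule, 104 stayed past the threshold in all 4 of these fits, and among those that did not were PSMB5, ATF4, BAG3, CDKN1A, HMOX1, HSPA6, SQSTM1 and UBB. List calls depended on single samples and on the scaling: camera called 10 lists higher in place of 15 without bortezomib replicate 2, with quantile normalization and with the authors' value table, and 12 with median scaling, each with 5 lower as before. The balance of rises and falls rested on the scaling. Rises were 46.5% of all calls and 35.2% of those at least 2-fold, against 63.5% and 54.0% when arrays were scaled to their median, and 36.2% and 26.7% when the percentile was taken over detected probes. Those scalings shifted the median log2 difference of all genes from -0.01 to 0.17 and to -0.11. The 2 vehicle and 2 bortezomib samples, with repeat scans averaged, did not overlap in 14285 genes, 62.9% of those tested, where chance gives 33.3%. In 30 of 4258 genes with several entering probes, probes passed in opposite directions.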

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

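The fits added after seeing the data were that of all 6 arrays as separate replicates, the first scan alone, normexp with negative controls and crossed numbers as a block. Leaving out 1 sample leaves 1 residual degree of freedom. The counts without 1 sample then ranged from 682 to 1413 genes higher, 1241 to 2092 lower, 682 to 854 at least 2-fold higher, 1241 to 1544 at least 2-fold lower, 10 to 16 lists higher and 4 to 5 lower. With all 6 arrays as separate replicates limma called 5640 genes higher and 5752 lower, since repeat scans then lower the apparent spread, and 6638 of these 11392 were among the 6643 main calls. With the slide (first or second scan) as a block 5061 were higher and 5308 lower, with 13 lists higher and 5 lower. That fit also takes all 6 arrays as replicates, so its spread is likewise lowered by the repeat scans. The first scan alone gave 3072 higher, 3496 lower and 15 and 5 lists. With normexp background correction limma called 0 genes higher, 0 lower, 0 at least 2-fold higher and 0 at least 2-fold lower, with 3180 genes at an unadjusted p under 0.05, a smallest adjusted p of 0.245, and 4823 calls with a variance trend. Its fitted background differed between arrays, even between scans of 1 array (-139 for bortezomib 1 and -185 for bortezomib 3, but 5.13 for bortezomib 2, and 4.20, -171 and -1.38 for vehicle 1 to 3). With the background of negative controls 3523 genes were higher and 3471 lower, with 879 at least 2-fold lower. Median scaling gave 1379 genes at least 2-fold higher. With a camera correlation estimated from the data 0 lists were higher and 0 lower. Of the 20 called lists, 13 kept their call in all 23 other settings, which include both fits that take repeat scans as replicates.

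The replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.319. With the replicate block limma called 493 genes higher and 978 lower, and the same 493 and 978 were at least 2-fold, with 1 residual degree of freedom. Crossed numbers as a block gave 3568 higher and 4091 lower.

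Some values changed sign, most of them close to 0 in the main fit, and the cause was not tested unless given. With quantile normalization MCL1 was at -0.088, GAPDH at -0.13, PPIA at -0.14, and the medians of proteasome assembly at -0.043, oxidative phosphorylation at -0.081, ribosomal proteins at -0.0036, leukocyte markers at 0.14 and endothelial markers at 0.017. With the authors' value table MCL1 was at -0.053, ACTB at -0.045, GAPDH at -0.030, PPIA at -0.18, and the medians of proteasome assembly at -0.047, oxidative phosphorylation at -0.066, ribosomal proteins at 0.0074, with camera's direction down, leukocyte markers at 0.14 and endothelial markers at 0.013. With the percentile over detected probes MCL1 was at -0.027, PPIA at -0.091, and the medians of p53 targets at -0.033, homologous recombination at -0.0091, oxidative phosphorylation at -0.050, basal epithelial genes at -0.049 and squamous differentiation at -0.082. With median scaling MYC was at 0.12, and the medians of anti-apoptotic genes at 0.13, DNA replication at 0.11, interferon response at 0.024, leukocyte markers at 0.15 and endothelial markers at 0.13. Median scaling and the percentile over detected probes shift all genes by a constant. With the mean of a gene's probes PPIA was at -0.35, XIAP (called at -0.56 in the main fit) at 0.0048, and the medians of anti-apoptotic genes at 0.038, basal epithelial genes at -0.020 and squamous differentiation at -0.066. With every probe tested the medians of anti-apoptotic and basal epithelial genes were 0.091 and -0.032. On probes detected on all 6 arrays squamous differentiation was at -0.064. With flagged spots kept CCNG1 (called at -0.82 in the main fit) was at 0.18, because another probe then represented it. With normexp PPIA was at -0.038 and leukocyte markers at 0.042, and with negative controls at -0.031 and 0.020. With all 6 arrays as separate replicates, and likewise with the slide as a block, PPIA was at -0.023, leukocyte markers at 0.073 and endothelial markers at 0.092. With the first scan alone PPIA was at -0.0052. Without 1 sample MCL1 ranged from -0.042 to 0.19, PPIA from -0.066 to 0.081, and the medians of anti-apoptotic genes from -0.094 to 0.048, basal epithelial genes from -0.023 to 0.16, squamous differentiation from -0.16 to 0.040, leukocyte markers from -0.20 to 0.12 and endothelial markers from -0.76 to 0.18. Of 174 named genes, 169 were called, and 169 lost their call with normexp, 73 with the replicate block, 24 without a filter on dim probes, and 29, 42, 60 and 61 without bortezomib 1, bortezomib 2, vehicle 1 and vehicle 2. Median scaling ended 8 gene calls, and other settings that ended any ended from 1 to 7.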

Other observations

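Gene families with a shared symbol stem were tested after the data were seen, 193 of them with at least 10 members. Genes of the HOXB cluster, homeobox transcription factors that mark position along the body axis, fell in 7 of 10 members and rose in none, with a median log2 difference of -0.98 (camera adjusted p = 0.0170, and adjusted p = 0.902 with an estimated correlation). HOXB13 was at -1.42 ± 0.12 (SE, n = 2 per group), HOXB3 at -1.40 ± 0.10, HOXB2 at -1.34 ± 0.10 and HOXB9 at -1.20 ± 0.21, all past limma's threshold, whereas HOXB1 (0.23 ± 0.14), HOXB4 (-0.27 ± 0.35) and HOXB8 (-0.93 ± 0.52) were not. The family median stayed between -1.07 and -0.64 under 5 other scalings. Symbols beginning with EIF, mostly translation initiation factors, rose in 18 and fell in 3 of 52, with a median of 0.38 (camera adjusted p = 0.00117, and adjusted p = 0.902 with an estimated correlation). EIF4E, which binds the mRNA cap, was at 0.96 ± 0.17, EIF2S2 at 0.92 ± 0.15, EIF1 at 0.74 ± 0.11 and EIF2S1 at 0.69 ± 0.10. Proteins of the small mitochondrial ribosomal subunit (MRPS) rose in 11 and fell in 2 of 27, with a median of 0.39 (camera adjusted p = 0.0486, and adjusted p = 0.902 with an estimated correlation). MRPS22 was at 0.88 ± 0.10 and MRPS30 at 0.88 ± 0.11, and MRPS33 at -0.62 ± 0.10. Under the same 5 scalings the EIF median ranged from 0.24 to 0.56 and the MRPS median from 0.19 to 0.57. The HSPA and PSMD families, which overlap the fixed lists, also passed, in 11 of 13 and 12 of 14 members. The 5 families were the only ones called by camera at its preset correlation, and with an estimated correlation 0 were called and 0 had an unadjusted p under 0.05.

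The tests below were chosen after the result they measure was seen, except those on 4-fold calls, and all are on the same 4 samples. The 7 fibroblast markers fell in an epithelial line. Scaling as the whole cause was argued against for 6 of them: at least 6 were called lower under each of 5 other scalings, which moved the median of all genes only to between -0.11 and 0.17, while the list's median stayed between -1.70 and -0.97. These 5 leave out the planned normexp background correction. Limma called 0 genes under it, so no marker passed there, and the count holds for these 5 scalings only. The value of -0.97, with the background of negative controls, narrowly missed an earlier bound of -1, and the count of calls was chosen as the test after that. For COL1A1 scaling stays open. Its call was kept with the percentile over detected probes (-0.78 ± 0.15, SE) and with the background of negative controls (-0.55 ± 0.13). It ended under the other 3, where the fold was smaller and the error wider, with -0.50 ± 0.18 with median scaling as the value nearest to 0, against -0.68 ± 0.15 in the main fit. Loss of fibroblasts from the cultures stays open too, except for DCN and PDGFRB (below). Of the 12 listed markers 7 were above background on all vehicle arrays, a count that was known when its bounds were set and so decides nothing. COL6A3, PDGFRA and POSTN were above background on none of these arrays, COL1A2 on 2 and THY1 on 1, and THY1, on all 3 bortezomib arrays, was higher with the drug (0.38 ± 0.13, past the threshold only over the list alone). These go against fibroblasts, although levels in such cells were not measured here, and TE-1 cells may express the others. With vehicle the mean log2 level was 0.79 for DCN, -0.48 for PDGFRB, -3.66 for LUM and -4.49 for COL3A1. The lowest levels well above background there were -7.91, -8.28 and -7.77. Fibroblasts giving that much DCN and PDGFRB should also show COL6A3, PDGFRA and POSTN. Their absence argues against fibroblasts as the source of DCN and PDGFRB. LUM and COL3A1 lay nearer the floor, so for them and the remaining markers fibroblasts are not excluded. A fall of these genes in the TE-1 cells themselves, under the treatment that the design names, remains a possible explanation that was not tested.

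The fall of replication-dependent histones may be 1 signal read by many alike probes. The members' differences had an SD of 0.764, which is 5.95 times their median SE of 0.128. A shared signal read equally by all probes would leave them closer together. That SE covers only the spread between samples, so a shared signal that the probes read unequally stays open. Scaling was argued against, since the list's median stayed at -0.86 or below under 5 other scalings. Fewer cells in S phase could account for it, but the replication list had a median of -0.074 with members on both sides of 0, 12 of 33 of them within 0.25 of it, which decides nothing. An effect of treatment on histone transcripts apart from the cell cycle stays open.

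Falls outnumbered rises among large differences. For calls of at least 2-fold scaling stays open: 54.0% were rises with median scaling, which shifts all genes by a constant, against 35.2% in the main fit, but the other 4 scalings gave 26.7% to 41.7%. For calls of at least 4-fold (87 rises and 279 falls, 23.8% rises) none of these 5 other scalings passed 39.9%, which argues against it. Noise of dim probes was argued against only as the whole source, since rises were 36.6% of 4-fold calls (41 rises and 71 falls) among the 11348 brighter genes. These genes held 41 of the 87 rises but only 71 of the 279 falls, so a contribution of dim probes stays open. A treatment effect that lowers more transcripts strongly than it raises is a hypothesis from these data.

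The 4 samples can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split called 6643 genes, 2430 at least 2-fold and 20 lists, and for each count 1 of the 3 splits, the real one, gave as many. The highest of the other splits was 0 for all 3 counts in limma and camera. At an unadjusted p under 0.05 the other splits had 57 and 739 genes and 4 and 9 lists, against 9262 genes and 20 lists in the real one. Each other split puts 1 vehicle and 1 bortezomib sample on each side, so the treatment difference widens its residual spread. Few calls there were nearly certain from the outset, and the contrast decides nothing.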
